A study of Mus musculus with 2 samples.

How the data were processed

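The series holds single-nucleus RNA sequencing of newborn mouse brain (postnatal day 0). It has 1 library labelled Celf2 knockout (KO) and 1 library labelled Celf2 heterozygous (het). Per the series' design text, each library is a pool of 2 hemibrains whose nuclei were purified by gradient ultracentrifugation and run on a droplet platform of 10x Genomics. The extraction protocol in the labels describes frozen sections on spatial slides instead. The files list 2866210 barcodes for the KO-labelled library and 2962835 for the het-labelled library, which a droplet run gives, and barcodes were treated as droplets. Celf2 encodes an RNA-binding protein that regulates splicing, mRNA stability and translation.

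The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, before any selection of nuclei, made with Cell Ranger 9.0.1 per the file headers. The submitters' processing notes name the mouse build mm10 and the tools Cell Ranger and Seurat. The annotation is not given in the sources used here. Of the 33696 gene identifiers in the files, 31961 (94.9%) matched GENCODE vM21 on GRCm38 and 1735 did not, so no coordinates are printed and chromosomes are those of the matched genes. No cell annotation by the authors was used here, and all cell class names were rebuilt.

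A barcode counted as a nucleus when its UMIs reached 10% of the 99th percentile among the 10000 largest barcodes of its library and when it had at least 500 genes. This gave a threshold of 5328.6 UMIs and 20656 nuclei in the KO-labelled library, and 4463.6 UMIs and 20254 nuclei in the het-labelled library. Nuclei with more than 5% mitochondrially encoded UMIs were left out (33 and 22). Scrublet scores were computed per library, but the automatic limit marked 0 doublets in each library, so nuclei with a score above the 92nd percentile of their library were left out instead, with ties at the limit kept (1473 and 1462 nuclei, 7.14% and 7.23%). This limit, the naming limits below and the sex-linked limits were set after seeing the data. In all, 19150 KO-labelled and 18770 het-labelled nuclei were kept.

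Both libraries were clustered together without integration. UMIs were scaled to 10000 per nucleus and log-transformed, 3000 variable genes were chosen over both libraries without Celf2, sex-linked and mitochondrially encoded genes, and 40 principal components, 15 neighbours and Leiden clustering at resolution 1 followed (scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Of 23 marker sets, those of cortical excitatory neurons were joined for naming, and a cluster took the name of the set with the highest mean log2 fold against the other clusters. It kept the name only with at least 3 markers raised by 1 on the log2 scale, a marker of its own among its top 10 genes by fold, at most 1 further top gene from any other set and no set with more of them, a median doublet score below 0.1 and at least 20 nuclei. This named 30 of 55 clusters, in 18 classes, with 64.8% of KO-labelled and 67.2% of het-labelled nuclei. The unnamed clusters held 35.2% and 32.8%. By reason, the shares were 18.2% and 18.5% for too few raised markers, 11.1% and 9.13% for the doublet score, 3.55% and 3.36% for no marker of their own among the top genes, 2.21% and 1.75% for markers of another class, and 0.0836% and 0.0107% for too few nuclei. Classes with at least 50 nuclei in each library were compared, which left out endothelial-like (44 and 80 nuclei), erythroid-like (48 and 47) and pericyte-like or smooth muscle-like nuclei (46 and 171).

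With 1 library per genotype there is no test between genotypes, and no p-value or standard error is given. UMIs were summed per library and class and scaled to CPM (UMIs of a gene per 1e6 UMIs). Ratios are log2 of KO over het with a pseudocount of 10 CPM. Intervals are 95% exact Poisson for counts, exact conditional binomial for ratios of counts and exact Clopper-Pearson binomial for shares. They cover counting error only, and no difference between the libraries has a replicate check. Named genes follow a rule of size. In cortical excitatory neuron-like nuclei they are the 10 highest and 10 lowest ratios among genes with at least 100 pooled UMIs and at least 20 CPM in one library, without sex-linked, mitochondrially encoded, haemoglobin and ribosomal protein genes and predicted models. In each of the 5 next largest named classes they are the 3 highest and 3 lowest. The sex-linked genes, here and in clustering, are Xist, Tsix, Ddx3y, Uty, Kdm5d and Eif2s3y. Other X-linked genes stayed in. In addition the text names Celf1 to Celf6 and the 2 highest and 2 lowest members of a gene list. Some genes that these rules pick are not reported here. For 28 gene lists, the median ratio over members with at least 50 pooled UMIs is given with its percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The marker sets, gene lists, rules and the first set of alternative settings were fixed before the data were examined.

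Barcodes with at least 500 UMIs and below 50% of the threshold were taken to hold free RNA. Their median UMI total was 938 in the KO-labelled library and 1641 in the het-labelled library. With that amount in each nucleus, free RNA makes up 7.58% of the UMIs of KO-labelled and 16.2% of those of het-labelled nuclei. One setting subtracts this amount, with the profile of those barcodes, from each class. Subtraction as such was fixed in advance, but not the barcode range or the amount. Nuclei of the KO-labelled library were also split by sex-linked UMIs. Nuclei with at least 5 Xist UMIs and at most 1 UMI of Ddx3y, Uty, Kdm5d or Eif2s3y are called female-like, and nuclei with at least 1 such Y-linked UMI and at most 3 Xist UMIs male-like. In ratios against het, only the KO-labelled library was filtered this way, and all kept het-labelled nuclei stayed in. The limits are on UMIs, so they also select nuclei by depth.

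On counts simulated from the cortical excitatory neuron-like sums (12802 genes, 200 of them changed), 95.2% of the intervals of the unchanged genes held the true ratio. The interval lay on the true side of 1 for 100% of the genes raised 2-fold, 98% of those lowered 0.5-fold, 76% of those raised 1.25-fold and 70% of those lowered 0.8-fold. Of simulated unchanged lists, 92% fell within the central 95% of random lists. Counts were drawn with counting error alone and list members at random. These shares therefore do not check differences between libraries or lists whose members vary together. With 20% free RNA added from a shuffled profile, the median size of the log2 error fell from 0.20 to 0.03 after subtraction. The profile and amount subtracted there were the ones added, so this does not check their estimate from barcodes. The barcode range and the amount used for free RNA were chosen after seeing the data, so every value after subtraction rests on that choice. Alternatives covered the UMI threshold, doublets, the mitochondrial limit, clustering resolution, thinning to 5000 UMIs per nucleus, the sex-linked subsets, the pseudocount, the scaling, the gene filter and free RNA.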

Results

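Nuclear RNA was profiled in newborn mouse hemibrain to compare a Celf2 knockout (KO) with a Celf2 heterozygote (het), in a study of Celf2 in cortical architecture and synapses. Each genotype had 1 library, made from a pool of 2 hemibrains, so there was no replicate and no test between genotypes. The KO-labelled library held 420375379 UMIs over all barcodes, of which 62.0% lay in barcodes called as nuclei. The het-labelled library held 449681753 UMIs, of which 46.3% did. The kept nuclei had a median of 10447 UMIs and 3491 genes in the KO-labelled library (19150 nuclei) and 8488 UMIs and 3184 genes in the het-labelled library (18770 nuclei). All intervals below are 95% and cover counting error only.

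Celf2 RNA did not separate the labels. Over all nuclei, Celf2 (ENSMUSG00000002107, chromosome 2 of GRCm38) stood at 5438 CPM (5428 to 5447) in the KO-labelled library and at 5300.2 CPM (5289.9 to 5310.5) in the het-labelled library, a log2 ratio of 0.04. The deleted part of the gene is not given in the sources used here, and UMIs from outside that part check nothing, so the direction of every difference below rests on the library labels alone. In cortical excitatory neuron-like nuclei, where Celf2 was most abundant, it stood at 11402 CPM against 10160 CPM (log2 ratio 0.17). The ratio was 0.20 in upper-layer-like and 0.13 in deep-layer-like nuclei. In GABAergic or glycinergic neuron-like nuclei of diencephalon, midbrain or hindbrain, Celf2 stood at 1572 CPM against 2098 CPM (-0.41), and in oligodendrocyte lineage-like nuclei at 2428 CPM against 3347 CPM (-0.46).

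Across the 15 named classes compared, Celf2 was lower in the KO-labelled library in 10 and higher in 5. With female-like nuclei alone it was lower in 8, and with male-like nuclei alone in 14. After subtraction of free RNA it was lower in 5 and higher in 10, with -0.04 in the GABAergic class and -0.22 in the oligodendrocyte lineage. Against het, the female-like nuclei of the KO-labelled library gave 0.27 in the cortical class and the male-like nuclei -0.13. Celf1, the closest paralog of Celf2, was lower in the KO-labelled library in 14 of the 15 classes, with 197 CPM against 226 CPM in cortical excitatory neuron-like nuclei (-0.19, also -0.19 after subtraction). With male-like nuclei alone Celf1 was lower in 11 classes, and the cortical ratio was -0.08. Celf4 was higher in 13 classes, but lower in 8 with female-like and in 8 with male-like nuclei alone, with 0.17 over all nuclei, 0.01 in the cortical class and -0.47 in astroglia-like nuclei. Celf3, Celf5 and Celf6 had cortical ratios of 0.04, -0.01 and -0.03.

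**Figure D1:**
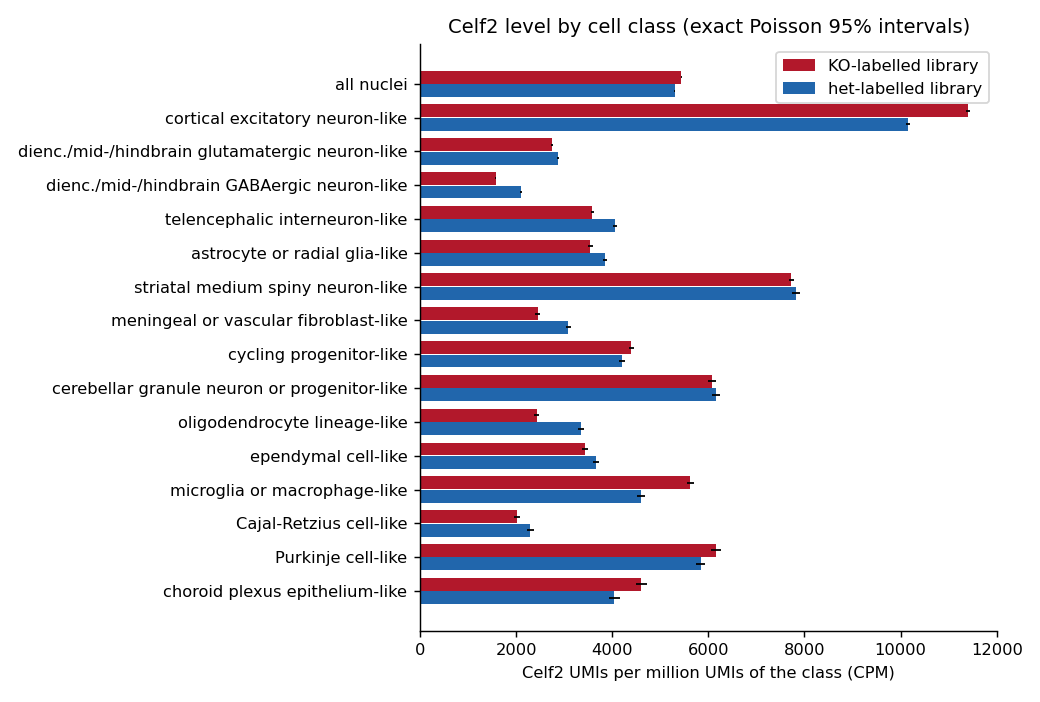
Celf2 level (CPM of each class sum, with exact Poisson intervals) in the KO-labelled and het-labelled libraries for each class of nuclei. Cortical excitatory neuron-like nuclei stand at 11402 CPM and 10160 CPM, and GABAergic or glycinergic neuron-like nuclei of diencephalon, midbrain or hindbrain at 1572 CPM and 2098 CPM.

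The pools differed in sex. A Y-linked UMI was present in 48.6% (47.9 to 49.3) of KO-labelled nuclei and in 0.266% (0.198 to 0.351) of het-labelled nuclei, where the estimated free RNA alone would bring one to 18.0% and 0.0406%. In the KO-labelled library 11561 nuclei were female-like, 3836 male-like and 3753 neither, and in the het-labelled library 92.3% were female-like. Nuclei with at least 5 Xist and at least 2 Y-linked UMIs, called mixed nuclei below, made up 14.4% of the KO-labelled library. By class the mixed nuclei went from 5.19% in cerebellar granule neuron-like to 38.5% in microglia-like or macrophage-like and 48.4% in choroid plexus-like nuclei. The estimated free RNA would bring 0.199 Y-linked UMIs per KO-labelled nucleus. Barcodes holding both a female and a male nucleus would look mixed, which was not tested, so kept nuclei may not all be single. Barcodes with nuclei of the same sex, and any in the het-labelled library, cannot be seen this way.

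Astroglia-like nuclei took a smaller share of the KO-labelled library than of the het-labelled library, 2.97% (2.73 to 3.22) against 5.79% (5.46 to 6.13). Meningeal or vascular fibroblast-like nuclei (2.26% against 4.01%), Purkinje cell-like nuclei (0.637% against 1.10%) and oligodendrocyte lineage-like nuclei (1.86% against 2.64%) also had smaller shares there. Striatal medium spiny neuron-like nuclei had a larger share, 4.78% (4.48 to 5.09) against 3.31% (3.06 to 3.58), as did cycling progenitor-like nuclei (3.13% against 2.48%). Cortical excitatory neuron-like nuclei made up 14.2% (13.7 to 14.7) against 12.9% (12.4 to 13.4). Within them, deep-layer-like nuclei held 4.68% against 3.83% of all nuclei and upper-layer-like nuclei 8.58% against 8.32%. The upper-layer clusters went apart: cluster 2 held 6.73% against 4.77%, and cluster 11, led by Gm29260, held 1.85% against 3.55% (355 and 666 nuclei). At resolution 2 the cluster led by Gm29260 held 303 and 365 nuclei. With 1 threshold on UMIs above the free RNA level in both libraries, the log2 ratio of cluster 11 went from -0.94 to -0.11, and that of the oligodendrocyte lineage from -0.50 to -0.00. With the UMI threshold doubled, cluster 2 went from 0.50 to 0.03, deep-layer-like nuclei from 0.29 to 0.12 and the cortical class from 0.14 to 0.02. Cycling progenitor-like nuclei went from 0.34 to -0.11 when male-like nuclei alone stood for the KO-labelled library. Clusters left unnamed for their doublet score are not in these shares, which hold for named clusters only. Cluster 9, highest for astroglial markers, held 3.51% of KO-labelled and 3.37% of het-labelled nuclei. Cluster 23, highest for oligodendrocyte lineage markers, held 1.33% and 1.41%, and cluster 28, highest for fibroblast markers, 1.01% and 0.794%.

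Glutamatergic neuron-like nuclei of diencephalon, midbrain or hindbrain made up 14.4% against 12.7% of nuclei (log2 ratio 0.18), and the GABAergic or glycinergic ones stood at a log2 ratio of 0.12. With 1 threshold on UMIs above the free RNA level in both libraries, these ratios changed sign, to -0.10 and -0.08. Telencephalic interneuron-like nuclei (5.94% and 5.77%), microglia-like or macrophage-like nuclei (1.36% and 1.43%) and Cajal-Retzius cell-like nuclei (0.914% and 0.852%) had overlapping intervals. Shares were smaller in the KO-labelled library for cerebellar granule neuron-like (2.01% against 2.65%), ependymal-like (1.52% against 2.17%) and choroid plexus-like nuclei (0.475% against 0.783%, with a log2 ratio of 0.36 in place of -0.72 when the UMI threshold was doubled). The UMI threshold was 5328.6 in the KO-labelled and 4463.6 in the het-labelled library, and astroglia-like nuclei were shallow, with medians of 7469 and 6243 UMIs. With the same threshold on UMIs above the free RNA level, the log2 ratio of the astroglial share was -0.51 in place of -0.97. Among the nuclei of the KO-labelled library, the astroglial share was 3.49% in female-like and 2.42% in male-like nuclei, and that of medium spiny neuron-like nuclei 4.01% and 7.06%. In the same order, cerebellar granule neuron-like nuclei held 2.62% and 1.15%, against 2.65% in the het-labelled library. Fibroblast-like nuclei held 2.30% and 3.52%, against 4.01% in the het-labelled library.

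**Figure D2:**
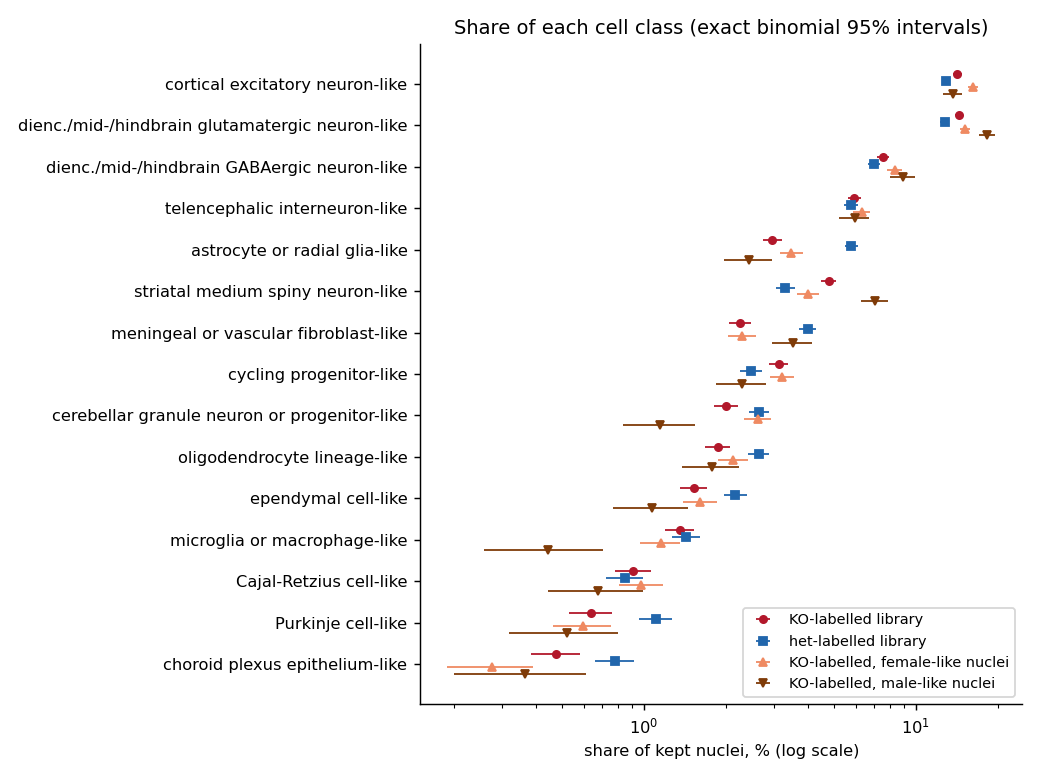
Share of nuclei (percent of kept nuclei, with exact binomial intervals) of each compared class in the KO-labelled and het-labelled libraries and in female-like and male-like KO-labelled nuclei, on a log scale. In the libraries astroglia-like nuclei make up 2.97% and 5.79%, and striatal medium spiny neuron-like nuclei 4.78% and 3.31%.

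In cortical excitatory neuron-like nuclei (2720 KO-labelled and 2420 het-labelled nuclei), the gene highest in the KO-labelled library among 5933 eligible genes was that of the membrane protein Tmem132a, at 69.1 CPM against 38.0 CPM (ratio 1.82, interval 1.67 to 1.98; log2 ratio 0.72). Others among the highest were Htr2a, a serotonin receptor (0.60), Arrdc3 (0.54) and the NADPH oxidase gene Nox4 (0.52). Snph, which anchors axonal mitochondria, stood at 0.46, the transcription factor gene Mef2c at 0.45 (2436 CPM against 1778 CPM), Cobll1 at 0.45, Iqcj at 0.41 and the nuclear export receptor gene Xpo1 at 0.41. All 9 genes kept at least 80% of their size after subtraction of free RNA. Female-like and male-like nuclei against het differed in size, with 0.17 and 1.57 for Htr2a, 0.22 and 1.08 for Cobll1, and 0.60 and 0.07 for Mef2c. The class differed in make-up, with cluster 2 at 47.4% of its KO-labelled and 37.0% of its het-labelled nuclei and cluster 11 at 13.1% and 27.5%.

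The 10 genes lowest in the KO-labelled library were led by Ndst4, a heparan sulfate-modifying enzyme, at 16.4 CPM against 43.8 CPM (ratio 0.374, interval 0.333 to 0.419; log2 ratio -1.03). Ttr, the abundant choroid plexus transcript, had a ratio of -0.94, Car10 -0.94, and the neuregulin receptor gene Erbb4, a marker of interneurons, -0.93 (403 CPM against 778 CPM). Nxph1, another interneuron marker, stood at -0.90, Dach1 at -0.84, Tpt1 at -0.84, Pcdh11x at -0.78, Spock3 at -0.77 and the striatal marker Ebf1 at -0.76. Free RNA made up an estimated 9.25% of the UMIs of this class in the KO-labelled and 19.6% in the het-labelled library. After its subtraction 8 of these 10 genes fell below 50% of their size, with -0.12 for Erbb4, -0.07 for Nxph1, -0.05 for Dach1, -0.48 for Ndst4 and -0.59 for Tpt1. Erbb4 after subtraction stood at -0.24 in female-like and -1.07 in male-like nuclei against het. By the same rule after subtraction, the highest ratio was that of the noncoding RNA Snhg11 (0.78, against 0.27 before), and Nrp2 (0.52) and Vwc2l (0.49) joined the highest 10. Female-like and male-like nuclei gave 0.36 and 1.61 for Snhg11, 0.18 and 1.12 for Nrp2, and 0.27 and 1.15 for Vwc2l. The lowest 10 then held Cebpz (-0.64), Efcab5 (-0.64), Bri3 (-0.55), Mthfd2 of the mitochondrial folate pathway (-0.53), Phex (-0.52), Blcap (-0.50) and the aminoacyl-tRNA synthetase genes Nars (-0.57), Lars (-0.52) and Cars (-0.50). After subtraction, female-like and male-like nuclei against het gave -0.78 and -0.08 for Bri3, and -0.40 and -0.86 for Mthfd2.

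Synaptic genes lay on both sides of 0 in cortical excitatory neuron-like nuclei. Of 30 presynaptic genes 15 were higher and 15 lower in the KO-labelled library, with a median log2 ratio of -0.00 at percentile 78.9 of matched random lists. Among them were the active zone gene Erc2 (0.30), Syn3 (0.17), Syt4 (-0.34) and the vesicular glutamate transporter gene Slc17a7 (-0.29). Of 24 postsynaptic genes 11 were higher and 13 lower (median -0.01, percentile 64.6), with Cnksr2 at 0.20, Shank1 at 0.18, Nrgn at -0.31 and Baiap2 at -0.22. Synaptic adhesion genes were higher in 22 of 36 cases (median 0.04, percentile 98.2; 0.10 after subtraction), with Tenm2 at 0.32 (10040 CPM against 8059 CPM), Tenm3 at 0.22, Slitrk4 at -0.37 and Cntnap2 at -0.27. Cntnap2 changed sign after subtraction (0.13), and Tenm2 was at 0.47 in female-like and -0.23 in male-like nuclei against het. Slc17a7 also changed sign in male-like nuclei (0.14), and the adhesion median was -0.11 in cluster 11 and -0.09 in male-like nuclei. Glutamate receptor genes were lower in 17 of 25 cases (median -0.06, percentile 1.55), such as Grik1 (-0.71), with Grin2d at 0.19 and Grin1 at 0.16. After subtraction their median was 0.00 and Grik1 stood at -0.08. GABA receptor genes had a median of -0.05, where the median over all genes of the class was also -0.05. Of them 3 were higher and 10 lower, with Gabra4 at -0.32, Gabrb1 at -0.27, Gabra3 at 0.21 and Gabra5 at 0.13. Voltage-gated channel genes had a median of -0.02 (percentile 29.8), with Kcnd2 at -0.34, Cacnb2 at -0.19, Cacna1a at 0.15 and Kcnma1 at 0.13.

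Layer identity genes were higher in the KO-labelled library on balance. Deep-layer genes were higher in 12 of 15 cases (median 0.09, percentile 99.7; 0.05 after subtraction), with the subcerebral projection neuron factor Bcl11b at 0.27, Ldb2 at 0.26, Nxph3 at -0.07 and Crym at -0.13. Their median was 0.10 in the deep-layer cluster 5 and -0.07 in the upper-layer cluster 2. Upper-layer genes were higher in 9 of 15 (median 0.07, percentile 99.2; 0.03 after subtraction), with Mdga1 at 0.29, Pou3f1 at 0.22, Lmo4 at -0.11 and the netrin receptor gene Unc5d at -0.31. Axon guidance genes were higher in 23 of 39 (median 0.04, percentile 99.8), with Nrp2 at 0.33, Epha3 at 0.30, Slit2 at -0.35 and Sema3c at -0.33. Neuronal migration and Reelin signalling genes were lower in 23 of 30 (median -0.10, percentile 0.00; -0.07 after subtraction). Erbb4 (-0.93) and the tubulin gene Tuba1a (-0.40) were the lowest of these, and Kif1a (0.14) and the Reelin adaptor gene Dab1 (0.14) the highest. In male-like nuclei against het Dab1 stood at -0.08 and Ldb2 at -0.05, and with 1 threshold above the free RNA level Unc5d stood at 0.06.

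Splicing factor genes were lower in the KO-labelled library in 22 of 32 cases in cortical excitatory neuron-like nuclei (median -0.07, percentile 0.48), and in 28 of 32 after subtraction (median -0.10, percentile 0.15). The lowest were Prpf4b (-0.27) and Srsf7 (-0.27), and the highest Hnrnpl (0.07) and Prpf8 (0.06). By cluster, members were lower in 18 of 32 cases in cluster 2, in 24 in cluster 5 and in 12 in cluster 11. The same list was lower in 26 of 32 cases in glutamatergic, 23 in GABAergic or glycinergic, 28 in interneuron-like, 24 in medium spiny neuron-like and 17 in astroglia-like nuclei. In the same order, the median log2 ratio over genes with at least 100 pooled UMIs was -0.036, -0.031, -0.026, 0.0009 and -0.0013. Neuronal RNA-binding protein genes were split, 20 higher and 21 lower (median -0.00, percentile 76.9), with Rbfox3 at 0.24, Igf2bp1 at 0.24, Mbnl2 at -0.27 and the splicing regulator gene Nova1 at -0.69, which stood at -0.06 after subtraction. In male-like nuclei against het Igf2bp1 stood at -0.05 and Mbnl2 at 0.01.

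Stress and housekeeping lists were lower in cortical excitatory neuron-like nuclei of the KO-labelled library. Integrated and endoplasmic reticulum stress genes were lower in 14 of 16 cases (median -0.14, percentile 0.00; -0.12 after subtraction), with the chaperone gene Hspa5 at -0.48, Slc7a11 at -0.38, Herpud1 at 0.05 and Pdia4 at 0.04. Cytosolic ribosomal protein genes were lower in 39 of 39 (median -0.44; -0.22 after subtraction; Rplp1 -0.81, Rplp0 -0.71, Rpl5 -0.16, Rpl15 -0.16), and at resolution 2 a cortical cluster led by Tpt1 and ribosomal protein genes held 35 KO-labelled and 137 het-labelled nuclei. Nuclear-encoded oxidative phosphorylation genes were lower in 31 of 34 (median -0.14; Uqcrh -0.47, Cox4i1 -0.43, Sdhb 0.01, Atp5c1 0.03). Mitochondrially encoded genes were higher in 11 of 13 (median 0.14, and 0.38 after subtraction). This list was set as a check of the pools and of free RNA. Such UMIs made up 0.230% of this class in the KO-labelled and 0.205% in the het-labelled library. A difference in the preparation of nuclei cannot be told apart. Medians were -0.09 for p53 and apoptosis genes (percentile 3.31; 0.03 in male-like nuclei against het), -0.05 for immediate early genes (17.8), -0.04 for interferon response genes (33.3), -0.03 for Wnt genes (43.7), -0.05 for Notch genes (20.7), 0.03 for S phase genes (99.9) and -0.00 for G2 and M phase genes (86.4). Lists of other cell types had medians of -0.10 for astroglial (percentile 0.1), -0.08 for oligodendrocyte maturation (3.91), -0.06 for microglial activation (17.1) and -0.09 for haemoglobin genes (6.88), where the median over all genes of the class was -0.05. The nuclear RNA Malat1, named after its value was seen, stood at 18941 CPM against 23876 CPM in these nuclei (-0.33; -0.21 after subtraction). The sex-linked list had 4 members higher and 2 lower (median 1.42).

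**Figure D3:**
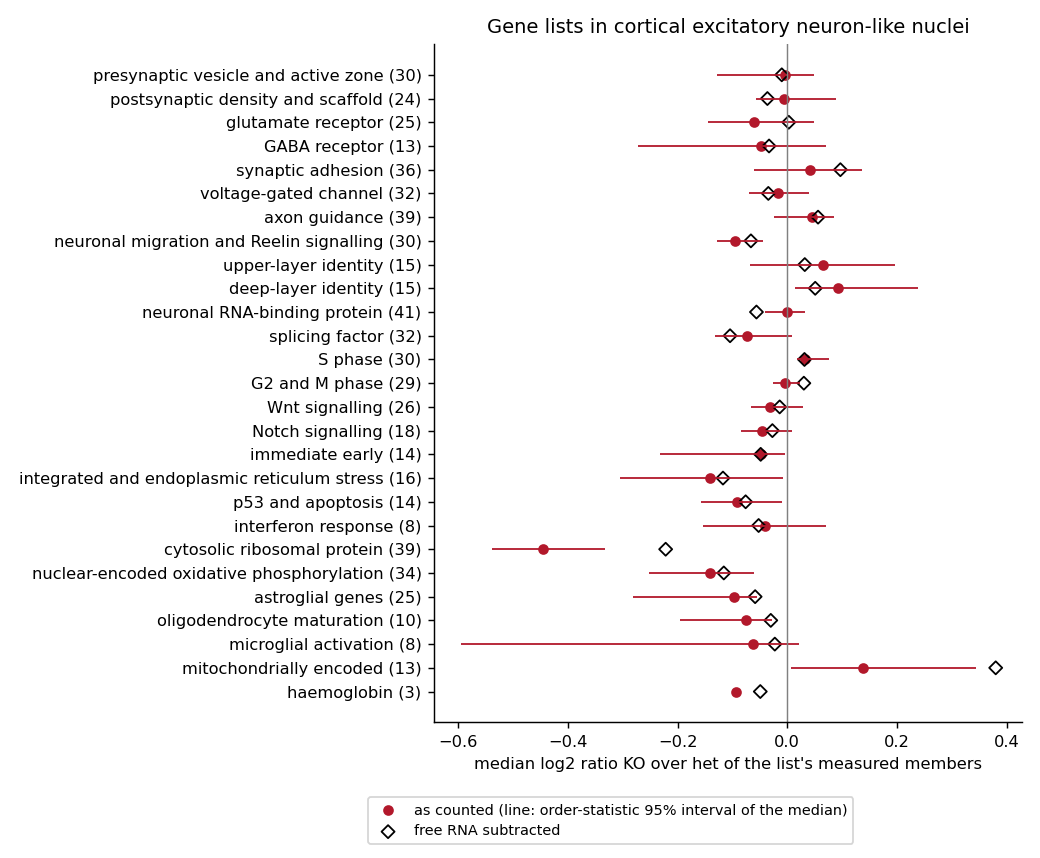
Median log2 ratio of KO-labelled over het-labelled CPM for each gene list but the sex-linked one in cortical excitatory neuron-like nuclei, before (with 95% order-statistic interval) and after subtraction of free RNA. Cytosolic ribosomal protein genes go from -0.44 to -0.22, and synaptic adhesion genes from 0.04 to 0.10.

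Tmem132a was higher in the KO-labelled library in other neuron classes too, at 0.80 in glutamatergic, 0.81 in GABAergic or glycinergic and 0.76 in interneuron-like nuclei. In glutamatergic neuron-like nuclei of diencephalon, midbrain or hindbrain it was followed by Kitl, the ligand of the Kit receptor (0.69), and Rnf220 (0.68). Rnf220 and Kitl were also the 2 leading genes of cluster 13, with 604 KO-labelled and 359 het-labelled nuclei of this class, and Ndst4 led a cluster of 85 and 207 nuclei at resolution 2. The lowest were Dlx6os1 (-0.87, and -0.32 after subtraction), Ndst4 (-0.80, and -0.87) and Tpt1 (-0.61, and 0.03). In the GABAergic or glycinergic class the transcription factor gene Mecom (0.75) and Fggy (0.51) followed, and Slc1a3 (-0.86) and Ptn (-0.71) were among the lowest, at -0.43 and -0.16 after subtraction. In interneuron-like nuclei Sfta3-ps (0.67) and Taco1 (0.59) were next highest, and Ttr (-1.05), Tpt1 (-0.91) and Ptn (-0.88) lowest, at -0.65, -0.57 and -0.29 after subtraction. Female-like and male-like nuclei against het gave 0.33 and 1.33 for Sfta3-ps, and after subtraction -0.94 and -0.05 for Tpt1. Glutamate receptor genes were higher in interneuron-like nuclei in 19 of 24 cases (median 0.11, percentile 99.9; 0.11 after subtraction), with cluster 8 at 66.4% of the KO-labelled and 56.0% of the het-labelled nuclei of this class and cluster 16 at 33.6% and 44.0%. In medium spiny neuron-like nuclei Otx2os1 (0.81), Itga8 (0.74) and the lymphoid factor gene Ikzf1 (0.61) were highest, and Ndst4 (-1.02), Ebf3 (-0.90) and Fabp7 (-0.88) lowest. Otx2os1, which also led a cluster of the GABAergic or glycinergic class, stood at 1.73 after subtraction and at -0.04 in nuclei with Xist and no Y-linked UMI.

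In astroglia-like nuclei astroglial genes were higher in the KO-labelled library in 24 of 28 cases (median 0.20; 0.05 after subtraction), with the metallothionein gene Mt2 at 0.49, Gfap at 0.46, Gja1 at -0.09 and Apoe at -0.36. Neuronal channel genes were lower there in 23 of 29 cases (median -0.30; -0.08 after subtraction). The highest single genes were Adamts18 (182 CPM against 88.0 CPM, 0.97), Adgrv1 (0.85) and Airn (0.84), and the lowest Lrfn5 (-1.25), Htr2c (-1.18) and Cdh9 (-1.15), which stood at -0.82, -0.65 and -0.95 after subtraction. Free RNA made up an estimated 11.6% and 24.3% of the UMIs of this class. Cluster 10 held 72.2% and 81.3% of its nuclei.

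In oligodendrocyte lineage-like nuclei genes of the maturation list were higher in the KO-labelled library in 15 of 16 cases (median 0.47; 0.33 after subtraction). The list also holds progenitor genes such as Pdgfra and Cspg4 and lineage genes such as Olig2 and Sox10. Its median therefore does not measure maturation alone. Enpp6, a marker of newly forming oligodendrocytes, stood at 102 CPM against 36.1 CPM (1.28), Bcas1 at 750 CPM against 382 CPM (0.96), Cnp at 0.05 and Sox10 at -0.02. After subtraction the list's median was 0.38 in female-like and 0.30 in male-like nuclei against het. Cluster 47, led by Bcas1, held 54 of 357 KO-labelled and 41 of 496 het-labelled nuclei of this class. In microglia-like or macrophage-like nuclei activation genes were lower in the KO-labelled library in 13 of 13 cases (median -0.31), with Lpl at -0.53, C1qa at -0.39, Apoe at -0.15 and C1qb at -0.15. The activation list also holds marker genes that served to name the class, such as C1qa, C1qb, Tyrobp and Trem2. Its median therefore does not measure activation alone. Mixed nuclei made up 38.5% of the KO-labelled nuclei of this class. Cluster 33, led by F13a1 and the macrophage marker Mrc1, held 55% of the KO-labelled and 52.8% of the het-labelled nuclei of this class. The activation median changed sign in female-like (0.50) and male-like nuclei (0.49) against het, each without the mixed nuclei. The het-labelled nuclei were not filtered, so the removal was one-sided.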

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

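The tests below were set before their results were seen, after the pattern itself had been noticed.

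Sex-linked UMIs, a signal that the labels do not mention, showed both female-like and male-like nuclei in the KO-labelled library: 48.6% of its nuclei held a Y-linked UMI, where free RNA alone would bring one to 18.0%, against 0.266% of het-labelled nuclei. A pituitary-like cluster led by the growth hormone gene Gh held 36 KO-labelled nuclei and 1 het-labelled nucleus. Gh stood at 4591 UMIs over all KO-labelled nuclei and was listed at 0 in het-labelled nuclei, and in barcodes taken to hold free RNA it stood at 107 CPM and 0.00495 CPM.

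The direction of Celf2 differed between classes, with a log2 ratio of 0.17 in cortical excitatory neuron-like nuclei and -0.41 in GABAergic or glycinergic neuron-like nuclei of diencephalon, midbrain or hindbrain. In male-like nuclei it was one direction, -0.13 and -0.74, and after subtraction female-like nuclei gave 0.22 and 0.02. The difference between the classes was not tested, since each genotype has 1 library.

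Celf2 was lower in the KO-labelled library in the GABAergic or glycinergic class. Free RNA remains open as a source, because its subtraction took the log2 ratio from -0.41 to -0.0426. A difference between animals or sexes within the KO-labelled pool remains open too, because female-like and male-like nuclei against het gave -0.36 and -0.74, a difference of 0.376. Genotype is the biological explanation that the design names, and with 1 library per genotype it was not tested apart from these. Free RNA may account for part of this ratio, since after subtraction female-like nuclei stood at 0.02 and male-like nuclei at -0.49.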

How the results depend on the processing

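The settings with 1 UMI threshold shared by both libraries, those above the free RNA level, the 3000 UMI threshold and the female-like and male-like nuclei were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library. The fixed threshold of 1000 UMIs lets 70305 and 152772 barcodes pass, most of them below the thresholds for nuclei, and was run for Celf2 over all these barcodes and not for classes, genes or lists, and nuclei with Y-linked UMIs and no Xist UMI gave no value because the het-labelled library holds almost none. The sign was kept in 259 of 287 values for the Celf family, 204 of 221 for class shares, 819 of 872 for list medians, 769 of 790 for list members and 952 of 955 for genes named by size. The pseudocount and the UMI filter cannot change a single gene's sign, and 184 of the list member and 294 of the named gene values moved beyond their counting interval. A further 8 and 3 lay beyond it with the sign reversed. In cortical excitatory neuron-like nuclei the splicing factor median stayed below 0 and the deep-layer median above 0 in every setting run for lists. None of these settings took single clusters of the class apart. In cluster 2 the deep-layer median was below 0, and in cluster 11 most splicing factor genes were not lower. Depth limits the shallow classes, since astroglia-like nuclei had medians of 7469 and 6243 UMIs against thresholds of 5328.6 and 4463.6, and free RNA weighs on the het-labelled library more than on the KO-labelled one.

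All values that follow are log2 ratios with the reported value in brackets, and the cause was not tested. Celf2 over all nuclei (0.04) was -0.0948 over all barcodes from 1000 UMIs, -0.0096 with the UMI threshold doubled, 0.0430 with no doublets left out, 0.0784 after thinning to 5000 UMIs, 0.095 in nuclei with Xist and no Y-linked UMI, 0.11 in female-like nuclei, -0.23 in male-like nuclei, 0.092 with median-ratio scaling and 0.0934 with free RNA subtracted. Celf2 in cortical excitatory neuron-like nuclei (0.17) was 0.13 with the threshold doubled, 0.10 at resolution 0.5, 0.19 at resolution 2, 0.15 after thinning, 0.266 with Xist and no Y-linked UMI, 0.27 in female-like nuclei, -0.13 in male-like nuclei, 0.14 with the same UMI threshold, 0.126 with the same threshold above free RNA, 0.22 with median-ratio scaling and 0.12 with free RNA subtracted. The median ratio over genes was -0.05 in each of these sets, and with this scaling the cortical ratios of Celf5 and Celf6 and the cortical medians of presynaptic, postsynaptic, GABA receptor, channel, RNA-binding protein, G2 and M phase and Wnt genes lay above 0.

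The astroglial share (-0.97) was -0.72 with the same UMI threshold, -0.51 with the same threshold above free RNA, -0.52 with a lower one above free RNA, -0.42 from 3000 UMIs, -0.70 with Xist and no Y-linked UMI, -0.73 in female-like and -1.26 in male-like nuclei. The cortical excitatory share (0.14) was 0.0248 with the threshold doubled, 0.28 from 3000 UMIs, 0.33 in female-like nuclei, 0.37 with Xist and no Y-linked UMI and 0.23 with the same threshold above free RNA. With the same and the lower threshold above free RNA, the glutamatergic share was -0.0991 and -0.0457 and the GABAergic share -0.0803 and -0.0414. The choroid plexus share (-0.72) was 0.36 with the threshold doubled, and the cycling progenitor share was -0.11 in male-like nuclei.

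Celf2 in astroglia-like nuclei (-0.12) was 0.074 with the threshold doubled and 0.11 with free RNA subtracted. In glutamatergic neuron-like nuclei (-0.06) it was 0.15 with free RNA subtracted, 0.0122 in female-like nuclei and 0.0076 with Xist and no Y-linked UMI, and in medium spiny neuron-like nuclei (-0.02) 0.15 in female-like nuclei and 0.16 with Xist and no Y-linked UMI. Celf1 there (-0.15) was 0.13 in male-like nuclei. In male-like cortical nuclei Slc17a7 was 0.14, Tenm2 -0.23, Dab1 -0.0819, Ldb2 -0.0455, Mbnl2 0.00814 and Igf2bp1 -0.0504. With Xist and no Y-linked UMI, Nrp2 was -0.0236 in cortical and Otx2os1 -0.0387 in medium spiny neuron-like nuclei. With free RNA subtracted, Tpt1 was 0.0253 in glutamatergic and Cntnap2 0.13 in cortical nuclei, and with the same threshold above free RNA Unc5d was 0.0638 in cortical nuclei.

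Among list medians in cortical excitatory neuron-like nuclei, male-like nuclei gave 0.12 for presynaptic (-0.00), -0.0937 for synaptic adhesion (0.04), -0.0437 for neuronal migration (-0.10) and 0.0290 for p53 and apoptosis genes (-0.09). Neuronal migration was -0.13 with Xist and no Y-linked UMI and -0.0395 with a pseudocount of 50 CPM. The interferon median of astroglia-like nuclei (0.19) was -0.31 and the S phase median of the oligodendrocyte lineage (0.19) was -0.10 with the threshold doubled. The ribosomal median of GABAergic nuclei (-0.33) was 0.0582 with free RNA subtracted. In microglia-like or macrophage-like nuclei the activation median (-0.31) was 0.50 in female-like nuclei, 0.493 in male-like nuclei and 0.80 with Xist and no Y-linked UMI. In the same class the interferon median (-0.45) was 0.12 in female-like nuclei and 0.17 with Xist and no Y-linked UMI. The presynaptic median (0.15) there was -0.27 in male-like nuclei and -0.0472 with Xist and no Y-linked UMI. The synaptic adhesion median of choroid plexus-like nuclei (0.38) was -0.62 in male-like nuclei and -0.13 with Xist and no Y-linked UMI.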

Other observations

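The split below of the genes shared by 6 classes into those higher and those lower in the KO-labelled library was tested only after the result was seen. Some values below passed the limit written for excluding an explanation. Those explanations were still kept open, for the reasons given with them.

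Further gene groups differed between the libraries in glia and epithelium. Astroglia-like nuclei had higher Wnt genes in the KO-labelled library in 19 of 25 cases (median log2 ratio 0.15; 0.05 after subtraction of free RNA) and higher interferon response genes in 9 of 10 (median 0.19; 0.13 after subtraction, but -0.31 with the UMI threshold doubled). Cell cycle genes were higher in oligodendrocyte lineage-like nuclei, 17 of 19 for S phase (median 0.19, but -0.10 with the threshold doubled) and 10 of 13 for G2 and M phase (median 0.17), and astroglial genes were lower there in 16 of 18 (median -0.38). Microglia-like or macrophage-like nuclei had lower interferon response genes in 14 of 14 cases (median -0.45, but 0.12 in female-like nuclei against het). They had higher presynaptic genes in 26 of 29 (median 0.15, but -0.27 in male-like nuclei), with 38.5% mixed nuclei in the KO-labelled library. Choroid plexus-like nuclei had higher synaptic adhesion genes in 29 of 30 cases (median 0.38, but -0.62 in male-like nuclei), with 48.4% mixed nuclei. Mitochondrially encoded genes were higher in 13 of 13 cases in glutamatergic (median 0.41) and 12 of 12 in GABAergic or glycinergic neuron-like nuclei (median 0.52). That list was set as a check of the pools and of free RNA, and a difference in the preparation of nuclei cannot be told apart.

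Over all nuclei, Ttr, the choroid plexus transthyretin, stood at 18.2 CPM in the KO-labelled and 54.5 CPM in the het-labelled library, and Ptgds, a prostaglandin synthase of meninges and choroid plexus, at 17.4 CPM and 52.4 CPM, where choroid plexus-like nuclei made up 0.475% and 0.783% and fibroblast-like nuclei 2.26% and 4.01%. The haemoglobin gene Hbb-bs stood at 19.3 CPM and 6.98 CPM, with log2 ratios of 1.14 in female-like and -0.43 in male-like nuclei against het. These genes were named after their values were seen. An unnamed cluster led by Tpt1 and ribosomal protein genes held 0.851% of KO-labelled and 2.68% of het-labelled nuclei.

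Named astroglia-like nuclei made up a smaller share of the KO-labelled library. The unnamed cluster 9, highest for astroglial markers, held 3.51% of KO-labelled and 3.37% of het-labelled nuclei and is not counted there. The sex or animal of the pools stays open: the higher of the female-like and male-like shares, 3.49%, lies below the lower ends of the het intervals, 5.46% for all and 4.98% for female-like nuclei, but these hold counting error only, and the spread between het animals is not known. The UMI threshold cannot be told apart from a smaller astroglial population. With the same threshold above free RNA the log2 ratio was -0.51 (-0.68 to -0.34). The value itself narrowly passed the limit written for excluding the threshold, but its interval holds that limit. The limit as written did not ask for the interval. Genotype, the biological explanation that the design names, stays open and was not tested apart from dissection and pool.

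Of 8033 genes tested in 6 classes, 4 were higher in all 6 by at least 0.3 on the log2 scale (Tmem132a, Arrdc3, Taco1 and Ccl28, with medians of 0.74, 0.44, 0.42 and 0.39) and 17 were lower, led by Ttr (-0.90), Fth1 (-0.65), Atp6v0c (-0.60), Ptgds (-0.58) and Ftl1 (-0.57). Free RNA cannot be told apart as a source for all together, which kept 61.3% of their median size after subtraction, for the lower genes (56.4%) or for the higher genes (95.2%), among which Taco1 went from 0.42 to 0.22. A difference between animals stays open too: the lower of the female-like and male-like medians was 98.8% of the higher, but the genes were picked on the pooled ratio, both subsets share the het-labelled library, and Arrdc3 stood at 0.57 and 0.06. DNA flanking the mutated locus stays open, with 2 genes on chromosome 2 where 1.71 were expected, a ratio of 1.17 with an upper limit of 3.72, and Tmem132a lies on chromosome 19. Genotype, the biological explanation that the design names, was not tested apart from these.

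After subtraction the same limit gave 2 higher genes, Tmem132a and Ccl28, and 4 lower genes, of which 0 were among the lower genes before subtraction. These were Atp6v0b of the vesicular proton pump (-0.49), the asparaginyl-tRNA synthetase gene Nars (-0.37), the amino acid transporter gene Slc38a2 (-0.36) and Timm44 of mitochondrial import (-0.34). Before subtraction Timm44 stood at -0.26 in female-like and 0.01 in male-like nuclei against het.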
